A study of Homo sapiens with 24 samples.

How the data were processed

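HepG2 is an established human hepatocellular carcinoma cell line. The series measured its RNA after growth in a radial flow bioreactor (RFB), in which medium flows through a bed of hydroxyapatite that carries the cells, or in plastic tissue culture plates. Per the labels, the bioreactor held 5 ml, the hydroxyapatite measured 0.6 to 1.0 mm, the plates were 60 mm wide, and the medium contained 10% fetal bovine serum. RFB cultures were harvested after 6 days and plate cultures after 5 days, so culture time went with the system throughout. Each system was cultured in 2 independent runs. From each run 3 samples were taken, from 3 portions of the bioreactor or from 3 plates, and each sample was measured on 2 Affymetrix human genome U133 GeneChips (array A), which gives 24 GeneChips from 12 samples and 4 cultures. The samples of a run share their culture and are not independent replicates of the system.

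The deposited values are linear probe set intensity values, 1 per probe set and GeneChip, made with MAS5 (version 5.0) per the submitters' processing notes. The 2% trimmed mean intensity of the deposited values lay between 2500.9 and 2501.0 on all 24 GeneChips, so the table had been scaled to a common level and was used with that scaling. The target and the background settings of that step are not given in the sources used here, and detection calls were not used here. Per the labels, 10 µg of total RNA entered the labelling of each sample.

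The table held 22283 probe sets. The 68 Affymetrix control probe sets were kept apart. Of the others, 19065 carried exactly 1 gene symbol in GEO's platform annotation, 1043 carried several and 2107 none, and only those with 1 symbol were used. Symbols were brought up to date through their Entrez identifiers with NCBI RefSeq's gene table (GRCh38.p14), in which 12 probe sets had no entry and kept the symbol of the platform annotation. These probe sets covered 11963 genes. A gene was represented by its probe set with the highest mean signal, and by a probe set with the suffix for cross-hybridising sequences only where it had no other. Named genes that rest on such a probe set include ACTB, CENPA, CYP3A43, CYP4F2, GAPDH, IDI1, MT1H, MT1X, MT2A, TUBA1B, TUBB2B and TUBB4B. Their values may include signal of related genes.

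Values were taken as log2(signal + 16), so fold changes understate the change of dim genes. Duplicate GeneChips were averaged, then the 3 samples of a culture, and the 2 RFB culture means were compared with the 2 plate culture means in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with an intensity trend) and Benjamini-Hochberg adjustment at 0.05. A gene was tested where the higher of its system means reached the median over all probe sets, a signal of 720, which left 7163 genes and set aside 4800. The other mean could lie below this level, as in plates for PFKFB4 (248), CENPE (139), HSPG2 (164), IGFBP2 (219) and SLC22A7 (311). The size of such a change is uncertain. An exact permutation test of 2 against 2 cultures cannot give a two-sided p under 0.333, so every call rests on the spread that limma pools across genes. The number of GeneChips and cultures limits the precision: the median standard error of a log2 change was 0.14. Errors given with log2 changes are limma standard errors from 2 cultures per system.

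The cultures of a system were compared with each other in limma on 3 sample means each. Those p-values measure only the spread between samples of a run. Numbered portions of the bioreactor were compared with a moderated F-test with culture as a term. In all, 47 gene lists were fixed before the data were examined and tested with camera (limma) at its preset correlation of 0.01, with the Benjamini-Hochberg adjustment over the 45 lists that had at least 5 tested members. The estimated correlation was run as an alternative. On the 4 culture means it leaves so few degrees of freedom that a call was hardly possible, so its adjusted p does not tell the lists apart. The named genes follow a rule also fixed before the data were examined. It takes the 8 largest rises and the 8 largest falls among genes with all 6 RFB samples on 1 side of all 6 plate samples, up to 4 members of each list that passed the test and up to 2 that did not, and 20 genes of drug metabolism, transport, regulation and reference use whatever their result. Only a part of the list members so named is described.

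The tests were tested on simulated data in which genes varied independently, with a spread drawn from the variance prior of limma. In the comparison of the systems over 7163 genes, 11.8% of genes changed by 0.5 on the log2 scale were called, 76.2% of those changed by 1 and 97% of those changed by 2. On average 5% of the calls were unchanged genes. For changes of 2, the comparison of the RFB cultures called 99.2% and the portion test 98.2%. The alternatives covered the normalisation, the pseudocount, the filter, the choice of probe sets, the GeneChips, the variance model, blocks for culture, and leaving out each culture or sample. With a plate culture left out, the spread comes from the RFB runs alone, so for named genes only the change is given. A cyclic loess normalisation, leaving out 1 GeneChip of low correlation, leaving out genes of very bright signal, an estimated correlation on the 12 samples, and other normalisations of the lists compared between cultures were added after seeing the data.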

Results

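Gene expression was measured in HepG2 cells grown in the RFB for 6 days and in plates for 5 days, with 2 independent cultures of each system, 3 samples per culture and 2 GeneChips per sample. The first question was which genes, among them those of drug metabolism and disposition, differed between the 3-dimensional culture and the plates. The mean correlation of a GeneChip with the others of its system, across probe sets, ranged from 0.921 to 0.931 in RFB and from 0.894 to 0.938 in plates. The lowest value belonged to the first GeneChip of plate sample 2 of culture 1. The ratio of 3' to 5' probe sets, a sign of RNA integrity, averaged 0.872 in RFB and 0.835 in plates for GAPDH (n = 12 GeneChips each) and 1.12 and 1.13 for ACTB.

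HepG2 cells in the RFB carried more RNA for DNA replication, mitosis, glycolysis and cholesterol synthesis than cells in plates, and less for the amino acid response and the unfolded protein response. These list calls rest on a preset correlation between genes. With an estimated correlation 0 of 45 lists were called on the 4 culture means (smallest adjusted p = 0.63), where few degrees of freedom make a call hardly possible. On the 12 samples, which counts samples of a run as independent, 1 was called, the amino acid response. There the estimated correlation was 0.68 for mitosis, 0.47 for DNA replication and 0.57 for the unfolded protein response, against 0.022 for the amino acid response. Of 7163 tested genes, 2469 differed (34.5%, limma), 1243 higher and 1226 lower in RFB. Of these, 615 differed at least 2-fold, 408 higher and 207 lower. Among all 2469 calls, 2073 had all 6 RFB samples on 1 side of all 6 plate samples. Of 1051 called genes with several probe sets, 801 had all of them on the same side. With 1 RFB culture left out, the calls numbered 546 or 619.

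The largest rise was of TNNI2, by 4.45 ± 0.30 on the log2 scale. It encodes a troponin subunit of striated muscle, as does TNNC1, the 7th largest rise at 3.65 ± 0.43. SLC2A3, a glucose transporter, rose by 4.18 ± 0.27, an 18.1-fold difference. Its level was lower in plate sample 2 of culture 1 (6.64) than in the other plate samples (8.53 to 9.24). CRIP2, a LIM domain protein, rose by 4.14 ± 0.29, and FSCN1, which bundles actin filaments, by 3.71 ± 0.28. GINS2, a part of the replicative helicase complex, rose by 3.78 ± 0.56, PFKFB3, whose product activates glycolysis, by 3.72 ± 0.45, and SCNN1A, a subunit of the epithelial sodium channel, by 3.63 ± 0.32. Of the 3 probe sets of SCNN1A, 2 lay on this side. The GINS2 call was lost under robust eBayes (adjusted p = 0.0588) and that of TNNC1 without RFB culture 1 (0.0637). The plate signals of these 8 genes lay below the filter level of 720, between 59.0 for TNNC1 and 437 for GINS2, so their folds depend on the pseudocount. They lay in the range of control probe sets for bacterial RNA, such as 537.8 in plates for a Thr probe set. The size and rank of these rises, among them the 18.1-fold difference of SLC2A3, are thus uncertain. The largest falls were of SLC17A2, of a phosphate transporter family, which fell by 3.46 ± 0.11 on the log2 scale from a plate signal of 11030 to 991, and of NAALADL1, a peptidase, which fell by 2.98 ± 0.34. LAMP3, a lysosomal membrane protein, fell by 2.79 ± 0.48, KCNMB3, a potassium channel subunit, by 2.48 ± 0.18, and SLC7A11, the cystine transporter, by 2.23 ± 0.11. LCAT, which esterifies cholesterol in plasma, fell by 2.20 ± 0.18, FBLN5, an elastic fibre protein, fell by 2.19 ± 0.32, and GFI1, a transcriptional repressor, by 2.17 ± 0.32. The RFB signals of LAMP3 (156), FBLN5 (178), NAALADL1 (231) and GFI1 (256) lay below the filter level, in the range of control probe sets for bacterial RNA such as 240.9 for a Dap probe set, so the size and rank of these falls are uncertain. Adjusted p over these 16 genes ran from 6.2e-05 for SLC17A2 to 0.0061 for LAMP3.

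In the list of DNA replication and nucleotide synthesis, 41 of 43 tested members rose and none fell, 41 when adjusted over the list alone, with a median change of 1.53. The list was called up (adjusted p = 2.7e-17), but not with its correlation estimated (adjusted p = 0.63 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, rose by 3.46 ± 0.44 and MCM5, of the replicative helicase, by 3.14 ± 0.48. POLE and RFC1 did not pass, at 0.42 ± 0.20 and -0.20 ± 0.17. POLE was at 0.66 without plate culture 2, and passed with no block (adjusted p = 0.0408). RFC1 was at -0.46 without plate culture 1, and passed with the mean of its probe sets (-0.52, adjusted p = 0.045). Of 50 mitosis and cell cycle genes, 49 rose, 50 when adjusted over the list alone, with a median of 1.96 (adjusted p = 8.7e-16, and adjusted p = 0.63 with an estimated correlation). CENPE, a kinetochore motor, rose by 2.70 ± 0.53, CCNA2, the cyclin of S phase and mitosis, by 2.53 ± 0.28, and the proliferation marker MKI67 by 1.15 ± 0.21. CENPA was at 0.64 ± 0.24 and did not pass. It passed with the replicate block (adjusted p = 0.0184), with culture as a random block (0.00715) and with no block (0.00359). Without plate culture 2 it was at 1.03. The calls of CENPE (adjusted p = 0.098 and 0.0751) and MKI67 (0.0572 and 0.0696) were lost without RFB culture 1 or 2, and that of MCM5 under robust eBayes (0.0614).

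Glycolysis genes rose in 17 of 19 cases, 18 when adjusted over the list alone, with a median of 0.98 (adjusted p = 7.1e-10, and adjusted p = 0.63 with an estimated correlation). ALDOC, an aldolase, rose by 2.38 ± 0.16 and PFKFB4, a relative of PFKFB3, by 1.93 ± 0.32, while HK2 and PFKM, a hexokinase and a phosphofructokinase, were at 0.29 ± 0.11 and 0.04 ± 0.15. HK2 was at 0.36 without plate culture 1. Of 28 hypoxia-inducible factor (HIF) targets outside glycolysis, 18 rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.00055, and adjusted p = 0.63 with an estimated correlation). BHLHE40, a circadian and hypoxia-responsive repressor, rose by 3.08 ± 0.46 and ADM, the vasoactive peptide adrenomedullin, by 1.91 ± 0.19, while STC2, a secreted glycoprotein that is also an ATF4 target, fell by 1.39 ± 0.11. The PFKFB4 call was lost without RFB culture 1 or 2 (adjusted p = 0.0718 and 0.0618) and the BHLHE40 call under robust eBayes (0.0596).

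Cholesterol synthesis genes rose in 15 of 19 cases, 17 when adjusted over the list alone, with a median of 1.03 (adjusted p = 1.5e-06, and adjusted p = 0.63 with an estimated correlation). IDI1, the isomerase of isoprenoid units, rose by 1.84 ± 0.21, TM7SF2, a sterol reductase, by 1.69 ± 0.11 and MVD, mevalonate decarboxylase, by 1.63 ± 0.28. Fatty acid and triglyceride synthesis had 11 of 19 members up and 4 down, also when adjusted over the list alone (adjusted p = 0.032, and adjusted p = 0.63 with an estimated correlation). FADS2, a desaturase, rose by 1.80 ± 0.19 and ELOVL6, an elongase, by 1.56 ± 0.14. With the second GeneChip of each sample alone, this list was no longer called (adjusted p = 0.063), at a median of 0.56 against 0.53. The MVD call was lost without RFB culture 1 or 2 (adjusted p = 0.0518 and 0.0609).

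The amino acid response list, targets of the transcription factor ATF4, had 27 of 34 tested members down and none up, 28 when adjusted over the list alone, with a median of -0.99 (adjusted p = 1.6e-12). With an estimated correlation it was lost on the 4 culture means (adjusted p = 0.63 with an estimated correlation). It was called on the 12 samples (adjusted p = 0.0014 with an estimated correlation), but this counts samples of a run as independent. CTH, which makes cysteine, fell by 2.00 ± 0.13, DDIT3, a stress-induced transcription factor, by 1.96 ± 0.10 and WARS1, tryptophanyl-tRNA synthetase, fell by 1.90 ± 0.15. ATF4 itself was at -0.25 ± 0.11 and VLDLR, a lipoprotein receptor, at -0.44 ± 0.15, and neither passed. Both passed with culture as a random block of the samples (adjusted p = 0.0432 and 0.0161) and with no block (0.0117 and 0.00418). ATF4 also passed under cyclic loess (-0.34, 0.0378), and VLDLR with the replicate block (0.0449). Without plate culture 1 ATF4 was at -0.256 and VLDLR at -0.603. Unfolded protein response genes fell in 16 of 25 cases and none rose, 17 when adjusted over the list alone, with a median of -0.71 (adjusted p = 2.5e-05, and adjusted p = 0.76 with an estimated correlation). HYOU1, a chaperone, fell by 1.66 ± 0.17, DNAJB9, a co-chaperone, fell by 1.62 ± 0.27, HERPUD1 by 1.57 ± 0.18 and SEL1L by 1.44 ± 0.23, the last 2 of the degradation pathway of the endoplasmic reticulum. The DNAJB9 call was lost without RFB culture 1 or 2 (adjusted p = 0.0523 and 0.0517).

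Of 33 actin cytoskeleton genes 17 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.00026, and adjusted p = 0.63 with an estimated correlation), among them TAGLN2, an actin-binding protein, by 1.99 ± 0.18 and FHL2, a LIM domain protein, by 1.24 ± 0.28. Tubulins and microtubule-associated proteins had 15 of 37 members up and 4 down, also when adjusted over the list alone (adjusted p = 0.0057, and adjusted p = 0.63 with an estimated correlation). The list median was only 0.18, with a mean of 0.45, and 18 members did not pass. TUBA1A rose by 3.20 ± 0.34, TUBB2B by 2.66 ± 0.24 and TUBB2A by 1.30 ± 0.16. Of 29 extracellular matrix genes and receptors 11 rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.03, and adjusted p = 0.63 with an estimated correlation). SPP1, osteopontin, rose by 2.15 ± 0.22, HSPG2, perlecan, by 2.04 ± 0.37 and SPARC by 1.30 ± 0.11. The matrix call was lost without very bright genes (adjusted p = 0.064), with the second GeneChips alone (0.0803), without RFB culture 1 (0.0565) and under both other filters, at medians of 0.17 to 0.32 against 0.31. Without RFB culture 1 or 2 the calls of HSPG2 (adjusted p = 0.0882 and 0.0897) and FHL2 (0.144 and 0.0576) were lost, as was that of HSPG2 with the second GeneChips alone (0.0578) and that of FHL2 with the first (0.0574). Fetal liver and carcinoma genes rose in 8 of 14 cases and fell in 1, with 9 up and 1 down when adjusted over the list alone (adjusted p = 0.0012, and adjusted p = 0.63 with an estimated correlation). KRT19, a keratin of bile duct and progenitor cells, rose by 3.08 ± 0.34, SOX4, a transcription factor, by 2.21 ± 0.13 and SPINK1, a trypsin inhibitor, by 1.94 ± 0.19.

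Further calls were made in 4 lists. The proteasome had 12 of 27 members up, 14 when adjusted over the list alone (adjusted p = 2.5e-05, and adjusted p = 0.63 with an estimated correlation), with PSMC3 of its ATPase ring at 0.96 ± 0.13. The median of this list was 0.3. Oxidative phosphorylation had 22 of 57 members up and 2 down, and 23 up when adjusted over the list alone (adjusted p = 2.5e-05, and adjusted p = 0.63 with an estimated correlation), with UQCRQ of respiratory complex III at 1.00 ± 0.12. The median of this list was 0.26. Immediate early genes rose in 9 of 23 cases, 11 when adjusted over the list alone (adjusted p = 0.001, and adjusted p = 0.63 with an estimated correlation), with the transcription factor KLF10 at 1.83 ± 0.14. Heat shock genes rose in 7 of 17 cases and fell in 1, with 8 up and 2 down when adjusted over the list alone (adjusted p = 0.03, and adjusted p = 0.63 with an estimated correlation). HSPB1, a small heat shock protein, rose by 2.31 ± 0.11 and DNAJB6, a co-chaperone, fell by 0.71 ± 0.14, a call lost without RFB culture 1 (adjusted p = 0.107). The heat shock call was lost under quantile normalisation (adjusted p = 0.082), with the mean of the probe sets (0.0918), under both other filters, without very bright genes (0.0861), without RFB culture 2 (0.058) and without plate culture 2 (0.22), at medians of 0.20 to 0.40 against 0.41.

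**Figure D1:**
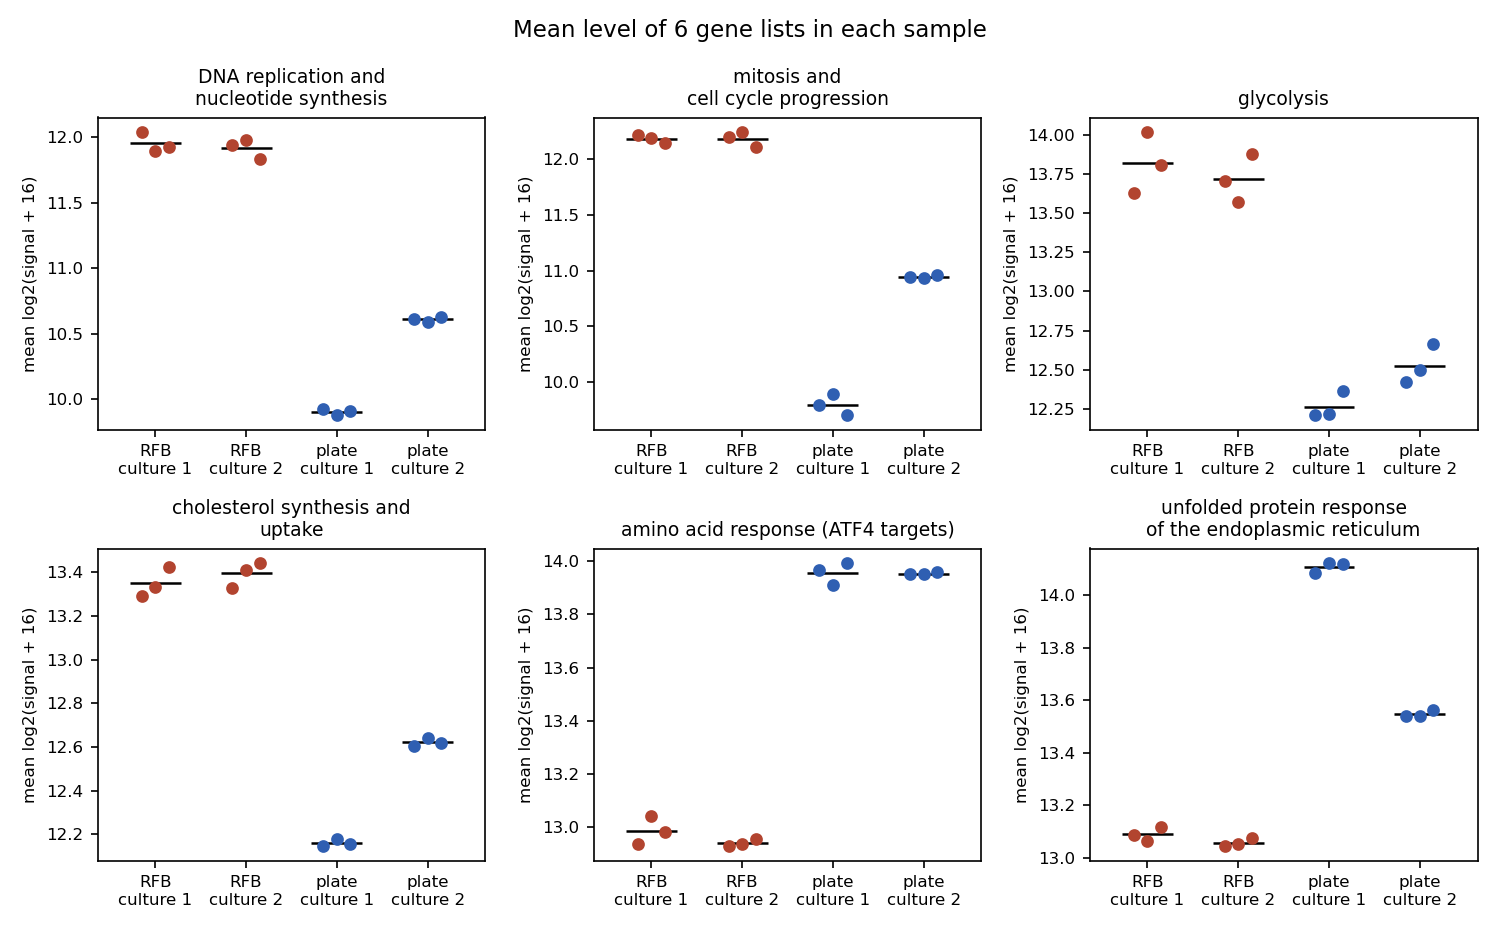
Mean log2(signal + 16) over the tested members of 6 gene lists (vertical axes, each with its own range) in each sample (points, 3 per culture, duplicate GeneChips averaged), by culture, with the culture mean as a line. All 6 RFB samples lie above all 6 plate samples in the first 4 panels and below them in the last 2, and the plate cultures stand at 9.80 and 10.94 for mitosis genes.

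The series was concerned with drug metabolism and disposition, and in these lists members moved in both directions. Of 8 tested cytochrome P450 genes, 1 rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.64). CYP4F2, a fatty acid hydroxylase, rose by 1.95 ± 0.38, its relatives CYP4F3 and CYP4F12 fell by 1.16 ± 0.17 and 0.63 ± 0.11, and CYP3A43 fell by 0.61 ± 0.17, a call lost with the second GeneChips alone (adjusted p = 0.336). The CYP4F2 value rests on 1 probe set with the suffix for cross-hybridising sequences, and the CYP3A43 value also on a probe set with this suffix. Both may include signal of related genes. The plate signal of CYP4F2, at 241, lay below the filter level, so the size of its rise is uncertain. Without RFB culture 1 or 2 the calls of CYP4F2 (adjusted p = 0.0983 and 0.0674), CYP4F12 (0.0591 and 0.0865) and CYP3A43 (0.212 and 0.0705) were lost. CYP1A1, the enzyme induced by aryl hydrocarbons, was at 0.40 ± 0.16 (adjusted p = 0.093). It passed with the first GeneChips alone (0.0491) and with no block (0.0186), and was at 0.585 without plate culture 1. The signals of CYP1A2, CYP2E1, CYP3A4 and CYP7A1 were too dim for the test, with CYP3A4 at 184 in RFB and 119 in plates and CYP7A1, the rate-limiting enzyme of bile acid synthesis, at 118 and 554. SLCO1B1, a hepatic uptake transporter, and NR1I3, a xenobiotic receptor, were likewise not tested. UGT1A1, NR1I2 and HNF4A were not analysed here, since no probe set carried their symbol alone.

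Other phase I enzymes rose in 8 and fell in 8 of 35 cases, with 11 up and 9 down when adjusted over the list alone (adjusted p = 0.83). ADH6, an alcohol dehydrogenase, fell by 1.62 ± 0.11, DPYD, which degrades pyrimidines, by 1.54 ± 0.24 and MAOB, a monoamine oxidase, by 1.29 ± 0.10, and ALDH1A1, a retinal dehydrogenase, rose by 1.45 ± 0.11. Of 26 phase II enzymes 9 rose and 3 fell, also when adjusted over the list alone (adjusted p = 0.36). UGT2B4, a glucuronosyltransferase, fell by 1.64 ± 0.25 and MGST3, a microsomal glutathione transferase, rose by 1.22 ± 0.13. SULT2A1, a sulfotransferase, was at 0.19 ± 0.19 and did not pass, and was at 0.49 without plate culture 2. Transporters rose in 5 and fell in 4 of 19 cases, also when adjusted over the list alone (adjusted p = 0.88), with a median of -0.18 and a mean of 0.04. SLC22A7, an organic anion transporter, rose by 1.83 ± 0.26 and ABCC3, an export pump, by 1.45 ± 0.16. ABCB4, the phospholipid exporter of bile, fell by 1.78 ± 0.15 and ABCB1, the multidrug exporter, by 0.58 ± 0.15. ABCC2 was at -0.17 ± 0.12 and did not pass, and was at -0.30 without plate culture 1. The ABCB1 call was lost with the first GeneChips alone, without the intensity trend, and without RFB culture 1 or 2 (adjusted p = 0.052, 0.054, 0.153 and 0.147), and the SLC22A7 call without RFB culture 1 or 2 (0.0518 and 0.0533).

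Nuclear receptors and liver transcription factors had 8 of 22 members down and 1 up, with 9 down when adjusted over the list alone (adjusted p = 0.03, and adjusted p = 0.63 with an estimated correlation). PPARGC1A, a coactivator of mitochondrial and gluconeogenic genes, fell by 2.02 ± 0.20, CEBPB by 1.52 ± 0.12, ESRRA, an orphan receptor, by 1.31 ± 0.11 and RXRA, the common partner of nuclear receptors, by 0.74 ± 0.14, a call lost with the mean of its 2 probe sets, which lay on different sides (adjusted p = 0.369), and without RFB culture 1 or 2 (0.084 and 0.0712). This list was no longer called without very bright genes, of which CEBPB was 1 (adjusted p = 0.064), though its median was -0.355 against -0.37.

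**Figure D2:**
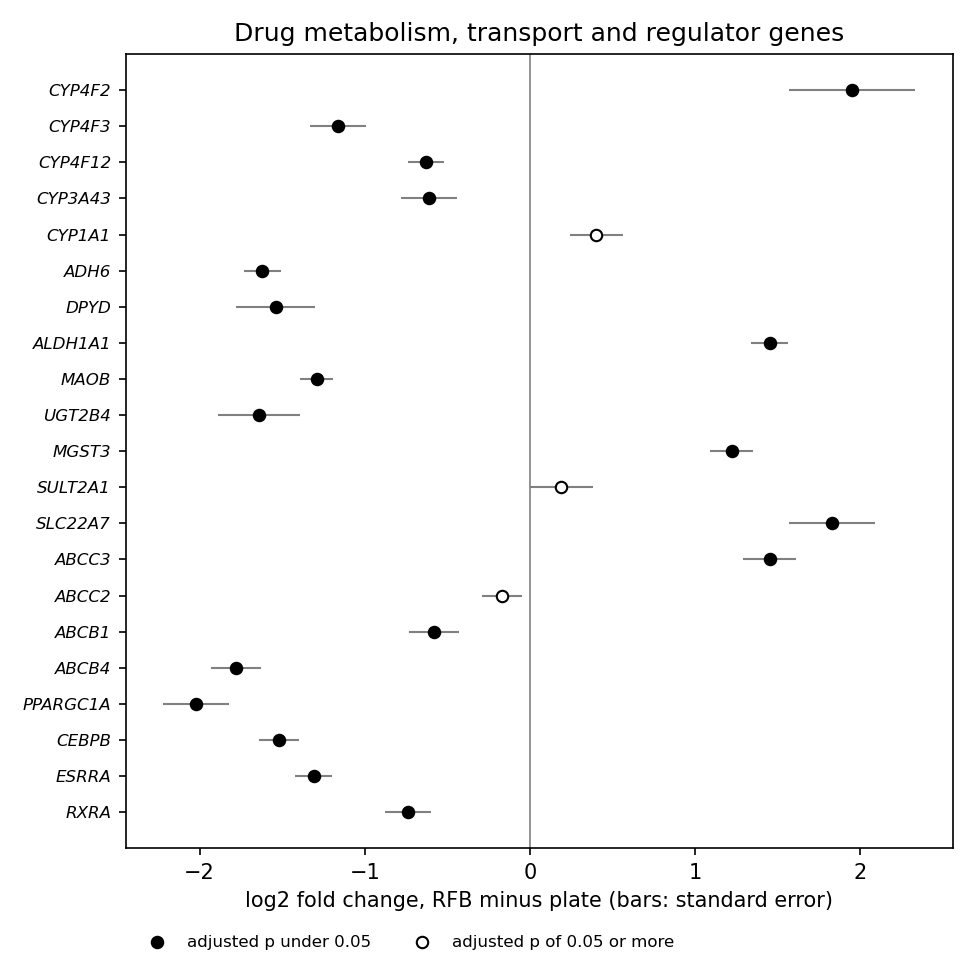
Log2 fold change, RFB minus plate (horizontal axis, points with limma standard errors from 2 cultures per system), of drug metabolism, transport and regulator genes, with filled points for adjusted p under 0.05. CYP4F2 (1.95) and SLC22A7 (1.83), both with plate signals below the filter level, lie farthest to the right and PPARGC1A (-2.02) farthest to the left.

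Hepatocyte plasma protein genes rose in 9 and fell in 13 of 43 cases, also when adjusted over the list alone, with a median of 0.01 and a mean of -0.12 (adjusted p = 0.58). The list was called down under quantile normalisation, with a median of -0.19 (adjusted p = 0.0469), and on the 22 members left without very bright genes, with a median of -0.48 (0.0219). SERPINC1, antithrombin, fell by 1.51 ± 0.12, F7, a clotting factor, by 1.17 ± 0.16 and APOM, an apolipoprotein, by 1.14 ± 0.10. ALB, albumin, rose by 1.09 ± 0.21 and AFP, alpha-fetoprotein, by 0.66 ± 0.17. The reference genes GAPDH and ACTB rose by 0.76 ± 0.17 and 0.66 ± 0.13, but the ACTB call was lost under quantile normalisation, at 0.19 (adjusted p = 0.189). With the second GeneChips alone the calls of AFP, GAPDH and ACTB were lost (adjusted p = 0.119, 0.0905 and 0.0512). Without RFB culture 1 or 2 those of ALB (adjusted p = 0.0854 and 0.0698), AFP (0.169 and 0.13), GAPDH (0.139 and 0.0876) and ACTB (0.115 and 0.0886) were lost. These 4 genes reached a signal of 46341 in the mean of at least 1 culture, where the brightest spike-in control, which is not cell RNA, also read higher in RFB, at 151232 ± 17454 (SD, n = 12 GeneChips) for cre-3 against 109613 ± 30737. SPP1, CEBPB, HYOU1, HERPUD1, RPL41, TUBA1B, TUBB4B, ATF4, MT1X and MT2A reached that signal as well. For ATF4, at -0.25 with signals of 46410 in RFB and 55190 in plates, the limit works the other way. A lower reading of bright signals in plates would hide a fall in RFB and not produce it. Acute phase and complement genes rose in 7 and fell in 7 of 26 cases, also when adjusted over the list alone (adjusted p = 0.93), with HAMP, hepcidin, up by 3.06 ± 0.25 and CP, ceruloplasmin, by 1.66 ± 0.25.

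Cytosolic ribosomal protein genes rose in 12 and fell in 5 of 52 cases, also when adjusted over the list alone, with a median of 0.15 (adjusted p = 0.20). The median was -0.14 under quantile normalisation (adjusted p = 0.283) and -0.46 over the 7 members left without very bright genes (0.0268). The list was called up with the brightest probe set of each gene whatever its suffix (0.21, adjusted p = 0.0235) and without plate culture 1 (0.30, 0.00181). RPL41 rose by 1.29 ± 0.27 and RPL36 fell by 0.76 ± 0.12. The RPL41 call was lost without RFB culture 1 or 2 (adjusted p = 0.0903 and 0.0783) and with the second GeneChips alone (0.0833), and the RPL36 call without RFB culture 2 (0.0725). For AKR1C1, BCL2, GSTM4 and RPL31 the probe sets of the gene lay on different sides, and these were taken as uncertain. Among markers of other cell types, none of 5 tested blood and immune genes rose or fell (adjusted p = 0.93). Of 6 cholangiocyte markers 3 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.33). KRT19 and SPP1 are given above, ANXA4, an annexin, rose by 0.97 ± 0.10, and SOX9, a transcription factor of bile ducts, fell by 0.45 ± 0.12. Of endothelial and of fibroblast and stellate markers, 1 and 3 were bright enough to test, and ACTA2, smooth muscle actin, fell by 0.46 ± 0.11 with 1 of its 2 probe sets on the other side. The calls of SOX9 (adjusted p = 0.192) and ACTA2 (0.291) were lost with the mean of their probe sets and without RFB culture 1 or 2 (0.166 and 0.204 for SOX9, 0.196 and 0.0822 for ACTA2), and that of SOX9 without the intensity trend (0.0544).

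The 2 runs of each system were compared next. Plate culture 2 had more mitosis, DNA replication and cholesterol synthesis RNA than plate culture 1, and less of the unfolded protein response. Of 7163 genes 997 differed, 610 higher and 387 lower in culture 2, 100 of them at least 2-fold (limma, 3 samples each). Mitosis genes were higher in 39 of 50 cases, with a median of 1.23 (adjusted p = 4.9e-26, and adjusted p = 0.021 with an estimated correlation), DNA replication genes in 17 of 43 (adjusted p = 3.5e-12, and adjusted p = 0.021 with an estimated correlation) and cholesterol genes in 12 of 19 (adjusted p = 8.3e-08, and adjusted p = 0.037 with an estimated correlation). Unfolded protein response genes were lower in 20 of 25 cases, with a median of -0.51 (adjusted p = 7.1e-17, and adjusted p = 0.021 with an estimated correlation). Metallothioneins and metal handling genes were higher in 7 of 16 cases and lower in 1 (adjusted p = 0.00066, and adjusted p = 0.12 with an estimated correlation). Cytosolic ribosomal protein genes were lower as a list, with a median of -0.30, 2 members higher and 2 lower (adjusted p = 3.6e-06, and adjusted p = 0.6 with an estimated correlation). Most of these genes are very bright, and the bright cre-3 spike-in, which is not cell RNA, moved the same way, from 16.85 to 16.53 on the log2 scale. The ribosomal call was lost under quantile normalisation (median -0.06, adjusted p = 0.12) and kept under cyclic loess (-0.21, 1.4e-05). Without very bright genes, 7 ribosomal members were left (adjusted p = 0.77) and the metallothionein call was lost (0.059), though the median of its 11 remaining members was 0.21 against 0.23. Named after their values were seen, CDCA8, of the chromosomal passenger complex, was higher by 2.90 ± 0.31, BIRC5, survivin, by 1.94 ± 0.12, and the metallothionein MT1H by 2.04 ± 0.07. MT1H rests on a probe set with the suffix for cross-hybridising sequences, as do MT1X and MT2A of the same list. The metallothioneins counted as higher may thus share signal. Without sample 2 of plate culture 2, 536 genes were called, and without its sample 3, 568.

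The RFB runs differed in 6 genes, all higher in culture 2 and none of them 2-fold. They were LGALS2, a galectin, CLTB, a clathrin light chain, PEPD, a peptidase, and the metallothioneins MT1F, MT1X and MT2A, named after their values were seen, with differences from 0.59 ± 0.09 for MT2A to 0.91 ± 0.13 for LGALS2 (limma, 3 samples each). MT1X and MT2A rest on probe sets with the suffix for cross-hybridising sequences. The metallothioneins may thus share signal and need not be separate differences. With 1 of the 6 samples left out, between 2 and 5 genes were called. At an unadjusted p under 0.05, 518 genes differed. As lists, metallothioneins and metal handling genes were higher in culture 2 (adjusted p = 0.00069, and adjusted p = 0.75 with an estimated correlation) and cytosolic ribosomal protein genes lower, with a median of -0.09 (adjusted p = 0.002, and adjusted p = 0.75 with an estimated correlation). The ribosomal call was lost under quantile and cyclic loess normalisation (adjusted p = 0.67 and 0.28), with cre-3 at 17.27 and 17.12 in cultures 1 and 2, and the metallothionein call without very bright genes (0.17), at a median of 0.13 against 0.16. It was kept under both normalisations (5e-04 and 0.00022), each at 0.16.

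The numbered portions of the bioreactor did not differ in any gene by the moderated F-test of limma (0 of 7163, smallest adjusted p = 0.31), with 306 genes at an unadjusted p under 0.05. The labels do not say that a number marks the same place in both runs, so the test cannot show that a reactor was uniform. The mean of the HIF targets outside glycolysis, chosen after its values were seen, was 12.264, 12.987 and 12.718 in the portions of RFB culture 1. In RFB culture 2 it was 12.443, 12.338 and 12.763. It lay between 11.892 and 11.97 in plate culture 1 and between 12.021 and 12.06 in plate culture 2. The median SD over genes was 0.197 between duplicate GeneChips in RFB and 0.198 in plates. It was 0.155 and 0.145 between samples of a culture, and 0.077 and 0.122 between culture means. These levels compare unlike units: single GeneChips, means of 2 GeneChips, and means of 3 samples. Averaging alone lowers the later values, and each value for cultures comes from only 2 means per gene. The values thus do not show that cultures vary less than duplicate GeneChips.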

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

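Apart from the other splits of the samples and the correlation taken from different plates, the tests given here and under the other observations were chosen after the results were seen.

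Among the very bright control probe sets, which entered no comparison, 5 read higher in all 6 RFB samples than in all 6 plate samples. The differences on the log2 scale were 0.62, 0.63 and 0.75 for the 3', 5' and middle probe sets of ACTB, 0.58 for Alu repeats and 0.57 for the 5' probe set of GAPDH. The bright cre-3 spike-in, which comes from the hybridisation mix and not from the cells, rose by 0.48 relative to the dimmer BioDn-3 spike-in of the same mix, where a shift common to the mix would give 0. The cre-5 and CreX-3 probe sets rose by 0.49 and 0.44, but the CreX-5 probe set, at 61620 and 62450, differed by only -0.02. A lower ceiling of bright signals on the plate GeneChips may therefore add to the rise of the brightest genes in RFB. A ceiling that depended on brightness alone is argued against as the whole cause of the ALB rise. Quantile normalisation, which undoes such a shift, left 0.93 and cyclic loess 0.97, both past the threshold. Neither undoes a ceiling that differs between bright probe sets, as the CreX-3 and CreX-5 values leave possible. Such a ceiling therefore stays open for ALB. For ACTB a ceiling cannot be told apart from a rise in the cells, with 0.19 and 0.50, of which the second was still called.

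Of 334 groups of 6 samples tested, list means and named genes in each system, 14 (4.19%) had a sample far from the other 5, and chance gives about 1 in 20. In RFB the gap as a share of the range was 0.628 for the mean of the transporters, 0.717 for the other phase I enzymes, 0.679 for CYP3A43 and 0.678 for BCL2, each with portion 2 of culture 1 lowest. It was 0.694 for POLE, 0.755 for ABCC2, 0.631 for DPYD and 0.726 for MAP1LC3B. In plates it was 0.665 for the growth factor list, 0.727 for SLC2A3, 0.679 for DNAJB6, 0.663 for CYP4F12, 0.656 for DPYD and 0.63 for SOX9.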

How the results depend on the processing

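Alternatives added after seeing the data were cyclic loess, leaving out 1 GeneChip, leaving out very bright genes, the estimated correlation on 12 samples, and both normalisations and leaving out very bright genes for lists between cultures. Calls between the systems numbered 2469 and lay between 1930 and 3275 in the other settings, except for 3876 for 12 samples with no block, which counts samples of a run as independent, and 546 to 3619 with 1 culture left out. With a culture left out the lone culture is assumed to vary like the other system, whose spread then sets the counts, and the runs of the RFB lay closer together than those of the plates. Calls of at least 2-fold were 615, and 383 to 787 with 1 culture left out. Genes higher in RFB made up 47.6% to 52.8% of calls. Leaving out the doubtful GeneChip gave 2433 calls, 612 of them at least 2-fold, and 1128 between plate cultures. The lists called, 14 up and 3 down, numbered 13 to 15 and 3 to 4 with 1 culture left out, and 12 to 15 and 3 to 4 over the other settings at the preset correlation. With an estimated correlation 0 and 0 were called on the 4 culture means, and 0 and 1 on the 12 samples, which counts samples of a run as independent. Between RFB cultures 2 to 5 genes were called with 1 sample left out, and between plate cultures 536 to 976. The portion test called 0 in each setting. The labels do not say whether cultures of the same number were run together. The difference of culture 1 and 2 in RFB and in plates correlated at 0.033 across genes, which gives no sign of a pairing over all genes. Metallothioneins were higher and ribosomal proteins lower in culture 2 of both systems. The ribosomal calls were lost under quantile normalisation in RFB and in plates (camera, adjusted p = 0.67 and 0.12). The cre-3 spike-in also read lower in culture 2 of both systems. With the replicate block 2530 genes were called (limma), and the adjusted p of MT2A went from 0.0467 to 0.000376. The block lowered the adjusted p of many other named genes as well and raised that of some. The change is thus not particular to MT2A. The MT2A call was lost in 11 other settings, among them quantile normalisation (adjusted p = 0.0707) and robust eBayes (0.217). Past the threshold in at least 1 of the settings compared, signs turned for AKR1C1 (0.39 with the mean of its probe sets and 0.85 with the brightest), BCL2 (0.027 with the mean), GSTM4 (-0.27 with the brightest) and RPL31 (0.32 with the brightest), and for the ribosomal protein list without very bright genes (-0.46). The medians of 15 lists, none of them called, turned sign in some setting, among them under quantile normalisation the ribosomal (-0.14), acute phase (-0.17) and plasma protein (-0.19) lists, the last then called. The cause was not tested.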

Other observations

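Genes of growth factor signalling, fixed as a list but not called at the main filter (7 up and 12 down of 30, 13 down when adjusted over the list alone, adjusted p = 0.18, but called down at a median of -0.65 with the filter at the 70th percentile, adjusted p = 0.00227), included INSR, the insulin receptor, which fell by 1.28 ± 0.12, IRS1, its adaptor, which fell by 1.23 ± 0.18, FGFR1, which fell by 1.34 ± 0.12 (5 of 6 probe sets on this side), and IGFBP2, which rose by 2.05 ± 0.31, a call lost without RFB culture 2 (adjusted p = 0.074). Among lysosome and autophagy genes (5 up and 12 down of 37, 14 down when adjusted over the list alone, adjusted p = 0.12, but called down without plate culture 1, adjusted p = 0.0307), LAMP2, a membrane protein, fell by 1.11 ± 0.11 and MAP1LC3B, an autophagosome marker, by 1.24 ± 0.16, and GM2A, an activator of ganglioside breakdown (5 of 6 probe sets on this side, adjusted p = 0.0517 without RFB culture 2), and GLA, a galactosidase, rose by 1.88 ± 0.31 and 1.24 ± 0.16. The junction genes CLDN4, CDH1 and CLDN6, of tight and adherens junctions, rose by 3.61 ± 0.28, 2.69 ± 0.31 and 1.71 ± 0.15 in a list with 8 up and 7 down of 30 (adjusted p = 0.91, median -0.11, mean 0.20). The plate signals of CLDN4 (142) and CDH1 (309) lay in the range of control probe sets for bacterial RNA, so the size of their rises is uncertain. Of 8 tested histone genes 4 fell and 2 rose, with H2AC6 down by 2.02 ± 0.13 and H2AX up by 1.87 ± 0.20, and TFR2, the hepatic transferrin receptor, fell by 1.63 ± 0.15, with 2 of 3 probe sets on this side.

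Plate culture 2 lay between plate culture 1 and the RFB: across 7163 genes, which are not independent, its difference from plate culture 1 correlated at 0.46 with the difference between systems, at 0.41 over the 6136 genes in no list, and the difference between RFB runs at -0.003. The plates enter both differences, but with the differences taken from different plates the correlation was still 0.30 to 0.38. The values from different plates argue against shared GeneChip noise, though the lowest only just met the bound of 0.3 written beforehand. It lay well above the 0.1 that noise alone would allow. The test is a weak one, since noise of like size in both plate cultures would largely cancel in the correlation of 0.46. A deviation of plate culture 1 alone would also raise it, but plate culture 2 minus 1 correlated at 0.22 with RFB minus plate culture 2 (0.18 or more with different plates), a difference that plate culture 1 does not enter and whose shared term lowers the value. The plate runs may thus have differed along part of the same axis as the systems, a hypothesis from 2 runs, with the seeding density not given here.

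The rise of the mitosis, DNA replication and cholesterol lists and the fall of the unfolded protein response list kept at least 97.9% of their medians under quantile and cyclic loess normalisation and without very bright genes. For the rising lists this hardly tests a lower ceiling of bright signals. None of 50 mitosis and 19 cholesterol members was very bright, and 42 of 43 DNA replication members were not. Such a ceiling on plate GeneChips would act against the fall of the unfolded protein response list in RFB, so it would not produce that fall. Plate culture 1 alone does not account for these list changes, since against plate culture 2 the medians kept 64.2% (mitosis, 1.26) to 83.8% (DNA replication, 1.28). Culture time, 6 against 5 days, went with the system and stays open beside an effect of the bioreactor.

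The amino acid response list parted from the unfolded protein response between the plate runs. Over its 33 members outside the other list, the median of plate culture 2 minus 1 was -0.02 (SD of members 0.22), where the proportion seen between systems would give -0.70. This is consistent with a fall of the amino acid response in RFB that is not the same shift as that of the unfolded protein response.

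The systems were split in 1 of 3 ways that 4 cultures allow. The real split called 2469 genes and the highest other 0. For plate cultures 1 of 10 splits of the 6 samples gave as many as the real 997, with 0 in the highest other. For RFB cultures 2 of 10 did, with 6 genes in the real split and 7 in the highest other. These designs have too few splits for a share under 0.05.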
